A study of Mus musculus with 12 samples.

How the data were processed

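Gene expression was measured with 1 microarray per sample in 12 samples of mouse bone cells sorted by flow cytometry. Per the labels, the cells came from bones of the limbs, skull cap, scapula, vertebrae and ribs, 3 osteoprogenitor populations named SSC, CSP and Thy were sorted, and total RNA was extracted in Trizol and labelled with biotin. The series' design text writes BCSP and Thy+ for 2 of these names, and the names are kept here as the sample labels give them. JUN was induced in young mice by doxycycline given to the mother in drinking water, and cells were sorted after 2 days of induction. Samples whose label carries -JUN are read here as the arm without induction. Each population has 4 arrays, 2 labelled JUN and 2 labelled -JUN, which makes 6 groups of 2.

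The deposited values are log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, normalises the arrays to a common distribution and summarises the probes of a probe set. Its software, version and settings are not given in the sources used here. The log2 scale was read from the values, which lay between 3.20 and 15.99. RMA compresses differences between dim probe sets, and a common distribution hides any change of the total amount of RNA. Scanner images or cell intensities were not analysed here, so the precision of a value rests on the number of arrays.

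The table holds 45101 probe sets, of which 64 controls were left out. A platform annotation gave 1 gene symbol for 34945 of the remaining 45037 probe sets, several symbols for 932 and none for 9160, and no gene was named from a probe set with several symbols. The Entrez identifiers of 34741 of the single-symbol probe sets were found in a reference gene table, and this changed 0 symbols. A probe set was kept when it lay above the median of its array in at least 2 arrays, which kept 26560. For a gene with several probe sets the one with the highest mean over all arrays was used, which left 12516 genes for testing out of 18193.

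Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 12516 genes and a threshold of 0.05. The effect of JUN in each population was the difference of the JUN and -JUN group means in a model of the 6 group means over all 12 arrays, with 6 residual degrees of freedom, so that each group of 2 was assumed to vary like the other groups. The average effect was the mean of the 3 differences with the mouse as a random block (duplicateCorrelation, consensus correlation -0.0602). Each mouse was either with or without JUN. For such an effect a negative correlation counts arrays of the same mouse as more than independent. The block therefore does not correct for shared mice here, and p-values of the average may be too low. Whether the effect differed between populations was tested with a moderated F test of the interaction. Populations were compared in a model of population and induction with 8 residual degrees of freedom, 4 arrays against 4. Errors given with differences are standard errors of the fit, and errors given with group means are standard deviations. P-values measure the spread between these samples.

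Gene groups were tested with camera from limma at its preset correlation of 0.01 between genes, with adjustment over the 40 lists that had at least 3 genes tested, out of 44 lists fixed in advance from textbook knowledge of bone, of AP-1 biology and of cell types that a bone sort can hold. The JUN comparisons were planned for this test. List tests on the population comparisons, and on differences of the JUN effect between populations, were added after seeing the data. Each list was also tested with a correlation estimated from the data, and no call in any of the 7 comparisons held with it. A count adjusted over the list alone corrects a gene's p-value for the genes of its list only.

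The groups, the tests, the lists, most of the alternatives and the rule for named genes were set before the data were examined. By that rule, each JUN comparison names Jun and, in each direction, up to 12 genes with the largest change among those that passed without overlap between the arrays. Where fewer than 5 passed in a direction, the genes of lowest p fill up to 5 and are given as values that did not pass. Each population comparison names in the same way up to 8 genes per direction, and the interaction names 10. From each list up to 4 members of lowest p may be named. Predicted and non-coding models, receptor and immunoglobulin segments and probe sets with several symbols were not named by their size.

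The titles name 5 mice, and 4 of them gave 2 or 3 of the arrays. Mice 3 and 3b were without JUN, mice 4 and 7 with JUN, and mouse 10 gave 1 SSC array without JUN. Arrays whose titles give the same mouse number are taken as the same animal. For mice 3 and 7 this joins a dated SSC title to undated CSP and Thy titles, which the labels do not settle, so the mouse blocks, the leave-outs of a mouse and the counts of mouse pairs rest on this reading. Within an induction state the replicate number follows the mouse, so it pairs the populations, and a mouse block is given beside a population comparison where it changes a count by over 1.5 times. After removal of the group means, the 10 pairs of arrays of 1 mouse correlated at -0.214 to 0.429, and 2 of these exceeded 0.1. With 2 arrays per group the deviations mirror each other, so these 2 pairs, of mice 4 and 7, are the same value (0.429) counted again. The replicate numbers do not name the same mouse in both induction states. Titles of 3 of the 4 SSC arrays carry a date, and no other title does. The fourth, SSC JUN replicate 1, and all CSP and Thy arrays are undated. A dated title may mark another processing day, so the population comparisons are also given with it as a covariate. In comparisons with SSC, this covariate or the removal of the dated arrays leaves the SSC level to SSC JUN replicate 1 alone. Such values cannot separate a processing day from that array.

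The statistical code was tested on simulated data with the gene means and spreads of these arrays, with 5 datasets of 12516 genes per comparison and, over the 5, 335, 335 and 330 genes changed by 1, 2 and 3 on the log2 scale. At a change of 2 on the log2 scale, the share of changed genes recovered was 55.5% for SSC, 46.3% for CSP and 48.1% for Thy. It was 88.1% for the average effect without the mouse block and 8.96% for the interaction. For the populations it was 78.5% for SSC against CSP, 82.1% for SSC against Thy and 84.2% for CSP against Thy. At a change of 1 the share was 4.18%, 2.69% and 0.896% for the JUN effect in SSC, CSP and Thy. A list shifted by 1 was called in 5 of 5 datasets in each of the 7 comparisons with a direction, with genes simulated as independent.

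Other choices set in advance were quantile normalisation, centring each array on its median, no filter, the mean of a gene's probe sets, a trended and robust prior, array weights, each array left out in turn, blocks for mouse and replicate number, and other choices of arrays. Added after seeing the data were a covariate for the sex of the mouse, a covariate for the poly-A labelling controls, the population comparisons without the dated arrays, the average effect with each mouse left out and no mouse block, the list tests with a mouse left out, and all list tests on the population comparisons and on differences of the JUN effect between populations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Osteoblast genes with no probe set of a single symbol, among them Runx2, Spp1 and Bglap, were not analysed here.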

Results

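The series asks what 2 days of JUN induction do to osteoprogenitors, and its arrays also let the sorted populations be compared. Of 12516 genes tested, none passed the threshold for an effect of JUN in any population, with 2 arrays against 2. With 4 arrays against 4, 54 genes differed between SSC and CSP, 49 between SSC and Thy and 124 between CSP and Thy. The counts are not alike in power. At a simulated change of 1, recovery was 0.896% to 4.18% for JUN in a population and 30.1% to 37.3% between populations. With each mouse as a block both counts for SSC were far lower, as given below. Values of any pair of arrays correlated at 0.872 to 0.979 across probe sets, and the first principal component held 37.4% of the variance. Xist, the transcript of the inactive X chromosome, lay between 12.59 and 13.53 in the 3 arrays of mouse 3 and between 6.11 and 7.29 in the other 9, so mouse 3 differs in sex from the rest.

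Jun itself, the gene to be induced, was among the brighter genes in every group. With JUN against without, its log2 value was 12.65 ± 0.74 against 12.33 ± 0.38 in SSC, 12.87 ± 0.07 against 13.30 ± 0.09 in CSP and 12.96 ± 0.09 against 13.23 ± 0.59 in Thy (mean ± SD, 2 arrays each). The differences were 0.32, -0.43 and -0.27 with a standard error of 0.41, at adjusted p = 0.804, 0.995 and 0.985 in limma. The average over the populations was -0.13 (SE 0.22, adjusted p = 0.774). A further Jun probe set read 11.98 with JUN against 12.14 without in SSC, 12.20 against 12.66 in CSP and 11.77 against 12.40 in Thy. Whether these probe sets read the induced transgene is not known from the sources used here, so the values neither establish nor exclude that JUN was induced. Without SSC JUN replicate 1 the difference of Jun in SSC was -0.20, and without Thy replicate 2 of the arm without JUN it was 0.15 in Thy. The average turned to 0.05 without SSC JUN replicate 2, to 0.01 without that Thy array and to 0.08 without mouse 7.

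**Figure D1:**
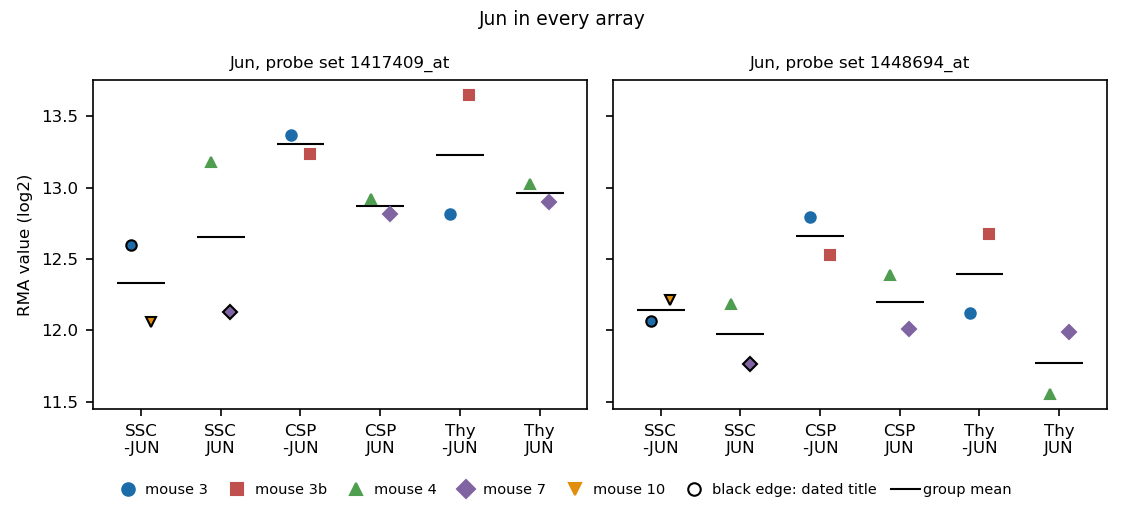
Log2 values of both Jun probe sets in each of the 12 arrays, by population and by induction, with 1 point per array. Group means of the brighter probe set run from 12.33 in SSC without JUN to 13.30 in CSP without JUN, and the JUN groups lie at 12.65, 12.87 and 12.96.

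In SSC, fat-related genes had lower values with JUN and cartilage genes had higher ones. Of 15 measured genes of adipocytes and CXCL12-abundant reticular cells, 13 were lower with JUN, by a mean of -0.52, and as a group they fell (adjusted p = 0.00347, and 0.229 with an estimated correlation). Lpl, which releases fatty acids from lipoproteins, differed by -2.04 ± 0.80, Fabp4, a fatty acid carrier, by -1.63 ± 0.56, and the adipocyte hormone Adipoq by -1.30 ± 0.58 (log2 difference ± SE, 2 arrays against 2). Of 24 chondrocyte genes 21 were higher, by a mean of 1.23, and the group rose (adjusted p = 0.0400, and 0.911 with an estimated correlation). Examples are Sox6, a regulator of cartilage formation, at 1.90 ± 0.83 and the cartilage collagen gene Col11a2 at 2.44 ± 1.66. None of the genes of these lists passed over all genes or adjusted over the list alone. Their values depend on single arrays. Without SSC JUN replicate 1, Lpl, Fabp4 and Adipoq stood at -0.61, -1.01 and -0.62 and Sox6 and Col11a2 at 0.58 and 0.23, and without SSC JUN replicate 2 at -3.48, -2.25 and -1.98 and at 3.22 and 4.65.

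Single genes in SSC did not pass in limma (0 genes, 813 at an unadjusted p under 0.05, 573 of them higher), and the values that follow all carry an adjusted p of 0.690. The lowest p among higher genes belonged to Ncan, which encodes a matrix proteoglycan of nerve tissue (3.09 ± 0.62), the glutamate receptor gene Grm3 (2.46 ± 0.50), the chemokine gene Cxcl14 (2.10 ± 0.43), Foxm1, a regulator of mitotic entry (1.47 ± 0.32), and Glb1l2 (2.10 ± 0.46). Among lower genes they were the zinc finger genes Zfp874a (-1.75 ± 0.42) and Zfp719 (-1.77 ± 0.46), Pcp2 (-1.53 ± 0.38), Ccbe1, needed for lymphatic growth (-1.67 ± 0.44), and Klhl2 (-1.27 ± 0.35). By the rule for naming, both JUN arrays lay on the same side of both arrays without JUN in each of these 10 genes. Cxcl14 passed when adjusted over the list alone, among cytokines and chemokines (adjusted p = 0.00921). Of 17 AP-1 family genes 15 were higher, by a mean of 0.42 (adjusted p = 0.441), with the JUN partner Junb at 1.20 ± 0.49. Of 16 textbook AP-1 targets 11 were higher, by a mean of 0.25 (adjusted p = 0.609), with the urokinase receptor gene Plaur at 1.24 ± 0.52. Other ligands of interest were Tgfb1 at 1.88 ± 0.69 and Bmp6 at 1.29 ± 0.40, and Il6 stood at -1.83 ± 0.74. Leaving out 1 array at a time moved Junb between 0.49 and 1.91, Plaur between 0.69 and 1.79, Tgfb1 between 1.11 and 2.65, Bmp6 between 0.80 and 1.78 and Ncan between 1.90 and 4.28. Il6 stood at -0.65 without SSC JUN replicate 1.

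The group results in SSC rest on few arrays. SSC JUN replicate 1, the only SSC array of mouse 4, had an AP-1 family mean of 11.77, against 10.62 to 10.92 in the other SSC arrays. Its AP-1 target mean was 10.76, against 10.08 to 10.36. Without SSC JUN replicate 1 the chondrocyte mean turned to -0.19, the AP-1 family mean to -0.15 and the AP-1 target mean to -0.04, and the adipocyte mean of -0.33 did not pass. The chondrocyte group also did not pass without SSC replicate 1 of the arm without JUN (1.55) or without either Thy JUN array (1.23). Without SSC JUN replicate 2 it stood at 2.65, the AP-1 family passed at 0.998, and 1 gene, Ncan, passed at 4.28. With a covariate for sex the chondrocyte mean of 0.66 did not pass, and with a covariate for the poly-A controls it turned to -0.59 and the adipocyte mean of -0.17 did not pass. These controls were themselves higher in both SSC arrays with JUN (10.2 and 11.2) than in both without (8.72 and 9.14).

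In CSP, genes of neutrophils and of skeletal muscle rose with JUN as groups. All 5 measured neutrophil genes were higher, by a mean of 0.73 (adjusted p = 0.00894, and 0.963 with an estimated correlation). These genes are dim. Their list means were 7.27 and 7.67 without JUN and 8.37 and 8.03 with it, and the medians of these arrays 7.66 to 7.73. S100a8 and S100a9, which encode the subunits of the neutrophil protein calprotectin, stood at 1.59 ± 0.45 and 0.88 ± 0.31 and passed when adjusted over the list alone, while 0 genes of the list passed over all genes. The granule protein genes Ltf and Camp stood at 0.53 and 0.45. All 11 skeletal muscle genes were higher, by a mean of 0.56 (adjusted p = 0.00894, and 0.963 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. They include Mylpf and Tnni2 of the contractile apparatus, at 1.05 ± 0.48 and 0.77 ± 0.34, the muscle creatine kinase gene Ckm at 1.01 ± 0.66 and the muscle regulator Myod1 at 0.60 ± 0.36. Without CSP JUN replicate 2 Ckm, Myod1 and Mylpf stood at 0.09, 0.12 and 0.50, and without CSP JUN replicate 1 at 1.94, 1.08 and 1.59. Without CSP replicate 1 of the arm without JUN Tnni2, S100a9 and Ltf stood at 0.40, 0.58 and 0.20, and without CSP JUN replicate 1 S100a8 stood at 0.88.

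Single genes in CSP did not pass in limma either (0 genes, 288 at an unadjusted p under 0.05), and each value here carries an adjusted p of 0.995. Of the higher genes, Popdc3 stood at 2.52 ± 0.55, the myosin-binding protein gene Mybpc1 at 1.20 ± 0.31, the small heat shock protein gene Hspb7 at 1.33 ± 0.37, Arhgef4 at 1.22 ± 0.32 and the tight junction gene Cldn19 at 1.45 ± 0.41. On the lower side were Mfsd4a (-2.01 ± 0.46), the neurotensin gene Nts (-2.05 ± 0.57), Zfp105 (-2.14 ± 0.57), Zfp934 (-1.23 ± 0.30) and Thap1 (-1.65 ± 0.40). By the same rule the arrays of the arms did not overlap in these 10 genes. Kif20a and Uhrf1, genes of mitosis and of DNA methylation upkeep in S phase, stood at 0.98 ± 0.30 and 1.02 ± 0.35. Of the 17 AP-1 family genes 12 were lower, by a mean of -0.18 (adjusted p = 0.245), and of the 16 AP-1 targets 9 were higher, by a mean of 0.09 (adjusted p = 0.874). The chondrocyte group had a mean of 0.24 (adjusted p = 0.998), with CSP arrays far apart within each arm. Leaving out CSP replicate 1 or CSP JUN replicate 1 made that mean -1.32 or -1.11. Leaving out CSP replicate 2 or CSP JUN replicate 2 made it 1.79 or 1.59, and each of these 4 passed. The neutrophil group did not pass without CSP replicate 1 of the arm without JUN (0.53), without CSP JUN replicate 1 (0.57) or with a covariate for sex (0.58). The muscle group did not pass without CSP JUN replicate 2 (0.22) or with dim probe sets kept (0.38). In the AP-1 lists, the target mean turned to -0.30 without CSP replicate 1 of the arm without JUN and to -0.24 without CSP JUN replicate 1. Without CSP JUN replicate 2 the targets passed at 0.41 and the family turned to 0.12.

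In Thy, skeletal muscle genes again rose as a group, with all 11 higher by a mean of 0.63 (adjusted p = 0.000987, and 0.975 with an estimated correlation). Tnnt3 and Tnnc2, genes of troponin subunits, stood at 1.15 ± 0.33 and 0.98 ± 0.54, Atp2a1, the calcium pump of fast muscle, at 0.77 ± 0.31 and the actin gene Acta1 at 0.97 ± 0.63. Leaving out 1 array at a time moved Tnnc2 between 0.54 and 1.43 and Acta1 between 0.65 and 1.30. None of the 11 passed over all genes or adjusted over the list alone. The genes closest to the threshold were Nsun7 (2.60 ± 0.35, adjusted p = 0.252) and the potassium channel gene Kcnd3 (3.36 ± 0.50, adjusted p = 0.303). Both were higher in each JUN array than in each array without JUN, which the rule for naming requires. Limma gave 0 genes past the threshold and 380 at an unadjusted p under 0.05.

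Other genes of lowest p in Thy were Evi2a (1.86 ± 0.35, adjusted p = 0.901), the muscle ubiquitin ligase gene Fbxo32 (1.71 ± 0.35) and Bud13 (1.44 ± 0.30) on the higher side. Lower values were those of Zfp418 (-3.21 ± 0.56, adjusted p = 0.647), Grk4, a kinase of G protein-coupled receptors (-2.76 ± 0.61), Zfp329 (-2.53 ± 0.53), Tmc7 (-1.86 ± 0.42) and Lix1 (-1.52 ± 0.31), the rest at an adjusted p of 0.985. Matrix remodelling genes Mmp3 and Timp1 stood at 0.83 ± 0.47 and 1.07 ± 0.73, the antimicrobial peptide gene Camp at 1.03 ± 0.37 and the bone regulator Dlx3 at -1.05 ± 0.42. The replication licensing genes Cdc6 and Mcm4 stood at -1.59 ± 0.68 and -1.25 ± 0.58, at -0.53 and -0.24 without Thy JUN replicate 1 and at -2.66 and -2.27 without Thy JUN replicate 2. Leaving out 1 array at a time moved Mmp3 between 0.46 and 1.21, Timp1 between 0.62 and 1.51, Camp between 0.53 and 1.53 and Dlx3 between -1.53 and -0.56. Of the AP-1 family 12 of 17 genes were lower (mean -0.09, adjusted p = 0.805). Of its targets 11 of 16 were higher (mean 0.16, adjusted p = 0.805), and the chondrocyte mean was 0.26 (adjusted p = 0.897). The muscle group did not pass without Thy JUN replicate 2 (0.69) or without Thy replicate 2 of the arm without JUN (0.34). Without the latter the AP-1 family mean turned to 0.33, and without Thy replicate 1 of that arm the family passed at -0.52, the target mean turned to -0.06 and the chondrocyte mean to -0.22. Without Thy JUN replicate 1 the target mean was -0.04, and without Thy JUN replicate 2 the AP-1 family mean lay just above 0.

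Averaged over the populations, no gene and no list passed. Limma with the mouse block gave 0 genes past the threshold and 1875 at an unadjusted p under 0.05 (15.0% of those tested). Of these, 1153 were higher with JUN. Without the block 1569 genes stood at an unadjusted p under 0.05, so the block with its negative correlation raised this count. The lowest adjusted p with the block was 0.326, shared by all genes named here. Higher values were those of Stac2 (1.72 ± 0.33), Kcnd3 (1.49 ± 0.28), Evi2a (1.03 ± 0.19), C1qtnf12 (1.12 ± 0.22) and the gut and brain peptide gene Cck (0.96 ± 0.18). Lower values were those of the ephrin receptor gene Epha5 (-1.69 ± 0.35), Zfp719 (-1.34 ± 0.25), Zfp874a (-1.18 ± 0.23), Pigg (-0.93 ± 0.19) and Lix1 (-0.82 ± 0.17). Among signalling genes, Tgfb1 stood at 0.95 ± 0.38, Bmp6 at 0.61 ± 0.22, the Wnt ligand genes Wnt5b and Wnt11 at 0.71 ± 0.22 and 0.58 ± 0.20, and Plaur at 0.78 ± 0.29. Uhrf1 stood at 0.65 ± 0.19, Atf2, a partner of JUN in AP-1, at -0.77 ± 0.27 and Pdgfra, a receptor of mesenchymal cells, at -0.70 ± 0.17. Leaving out an array or a mouse moved Tgfb1 between 0.55 and 1.36, Plaur between 0.34 and 1.22 and Atf2 between -1.05 and -0.47.

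As groups, tested without a mouse block, 12 of 15 adipocyte and reticular genes were lower on average (mean -0.28, adjusted p = 0.0762, and 0.717 with an estimated correlation). Adipoq stood at -1.07 ± 0.31 and Lpl at -1.18 ± 0.45. All 11 muscle genes were higher (mean 0.38, adjusted p = 0.0762, and 0.954 with an estimated correlation), as were all 5 neutrophil genes (mean 0.43, adjusted p = 0.166, and 0.954 with an estimated correlation). Of the latter, Camp, S100a8 and S100a9 passed when adjusted over the list alone, at 0.77 ± 0.20, 0.74 ± 0.25 and 0.43 ± 0.17, and 0 passed over all genes. Leaving out an array or a mouse moved Lpl between -1.93 and -0.44, and without CSP JUN replicate 1 S100a8 stood at 0.48. The AP-1 family had a mean of 0.05 while its test pointed lower (adjusted p = 0.880), and its targets had a mean of 0.17 (adjusted p = 0.880). The count of genes depends on the 3 JUN arrays of mouse 7. Without that mouse JUN rests on mouse 4 alone, which is assumed to vary like the others, and 1537 genes passed (475 higher and 1062 lower), or 495 without a mouse block. Leaving out any of the other 4 mice gave 0 genes in limma and 461 to 2103 at an unadjusted p under 0.05.

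These averages lie close to the threshold, and leaving out an array or a mouse moved several past it. The adipocyte group passed without SSC JUN replicate 2 (-0.34), SSC replicate 3 or CSP replicate 1 of the arm without JUN (-0.28 each), Thy replicate 1 of that arm (-0.31), Thy JUN replicate 1 (-0.25), CSP JUN replicate 2 (-0.24), mouse 10 (-0.28), mouse 3 (-0.31) or mouse 4 (-0.23). The muscle group passed without SSC replicate 3 (0.40) or Thy replicate 1 (0.48) of the arm without JUN, CSP JUN replicate 1 (0.48), SSC JUN replicate 1 (0.55), mouse 10 (0.40) or mouse 4 (0.62). The neutrophil group passed without CSP JUN replicate 2 (0.46) or mouse 3b (0.58). The AP-1 family mean turned to -0.01 without CSP replicate 1 and -0.09 without Thy replicate 1 of the arm without JUN. It turned to -0.02 without CSP JUN replicate 1 or Thy JUN replicate 1, to -0.16 without SSC JUN replicate 1 and to -0.10 without mouse 3. Without mouse 4 it passed at -0.26 and the target mean turned to -0.09.

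Whether the JUN effect differed between the populations was tested for each gene, and 0 genes passed in limma, with 144 at an unadjusted p under 0.05. The lowest p belonged to Nsun7, with JUN effects of -0.58 in SSC, 0.16 in CSP and 2.60 in Thy, and to Zfp418 at 0.83, -0.64 and -3.21. Grm3 (2.46, -0.15 and -0.74), Ncan (3.09, -0.13 and -0.84) and the catenin gene Ctnnd2 (2.54, -0.84 and -1.03) had their highest values in SSC. Kcnd3 (0.69, 0.41 and 3.36) had it in Thy and Arhgef4 (-0.48, 1.22 and -0.74) in CSP. Sfrp5, a secreted inhibitor of Wnt signalling, stood at 0.64, 0.18 and -1.35, Btbd18 at 1.02, -0.86 and -0.98 and the laminin gene Lama3 at 1.49, 0.54 and -0.89. The adjusted p was 0.9997 for each of these 10 genes. At a change of 2 in 1 population simulated data gave a recovery of 8.96%, so a difference in the response is not excluded.

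Against CSP, SSC were marked by genes of Schwann cells. Reln, a secreted protein gene, was higher by 4.40 ± 0.30 (log2, 4 arrays against 4, adjusted p = 4.91e-05) and the myelin gene Mbp by 4.47 ± 0.52 (adjusted p = 0.00339). The glial gap junction gene Gjc3 was higher by 4.20 ± 0.42 (adjusted p = 0.00228) and the endothelin receptor gene Ednrb by 4.09 ± 0.43 (adjusted p = 0.00250). The Schwann cell regulator Sox10 (2.80 ± 0.35, adjusted p = 0.00368), the hedgehog ligand of Schwann cells Dhh (3.86 ± 0.48, adjusted p = 0.00368) and the myelin protein gene Mal (3.93 ± 0.43, adjusted p = 0.00297) were higher as well. So were the glial and stem cell factor Sox2 (4.38 ± 0.70, adjusted p = 0.0176) and the myelin lipid carrier Pmp2 (4.58 ± 0.88, adjusted p = 0.0496). All 9 were higher in each SSC array than in each CSP array, which is a condition of being named by size. Of 12 genes of Schwann cells and neurons 8 were higher, 3 passed over all genes and 4 adjusted over the list alone, the additional one being the neuronal tubulin gene Tubb3 (1.39). Their mean was 1.14 (adjusted p = 1.97e-07, and 0.144 with an estimated correlation).

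Endothelial genes were lower in SSC than in CSP. Of 13 such genes 11 were lower, by a mean of -0.87 (adjusted p = 1.97e-07, and 0.144 with an estimated correlation), 2 passed over all genes and 6 adjusted over the list alone. Mmrn2, a gene of the vessel matrix, fell by 1.81 (SE 0.26, adjusted p = 0.00995) and Eng, a TGF-beta co-receptor that is also a surface marker in such sorts, fell by 1.57 (SE 0.24, adjusted p = 0.0132). Since the gates are not given, the difference of Eng may be set by the sort. The junction gene Cldn5 (-2.46 ± 0.52, adjusted p = 0.0848) and Tie1 (-1.45 ± 0.38, adjusted p = 0.216) did not pass. The other lower genes were Aplnr, the receptor of apelin (-1.34 ± 0.20, adjusted p = 0.0120), Tmem204 (-1.98 ± 0.37, adjusted p = 0.0446), Gpatch2 (-1.09 ± 0.20, adjusted p = 0.0392) and Jade1 (-1.04 ± 0.17, adjusted p = 0.0226). By the rule for naming, each was lower in all 4 SSC arrays than in all 4 CSP arrays. Genes of pericytes and smooth muscle rose as a group, with 9 of 14 higher, by a mean of 0.49 (adjusted p = 0.000130, and 0.294 with an estimated correlation), 0 passing over all genes and 6 adjusted over the list alone. Contractile genes lead them, with Acta2 at 1.10 ± 0.22, Tagln at 1.08 ± 0.25, Cnn1 at 1.04 ± 0.24 and Myh11 at 2.08 ± 0.51. The pericyte genes Rgs5 and Higd1b were not among the higher ones, since their fall against Thy, given below, was larger in SSC than in CSP. Neutrophil genes fell as a group, 5 of 5 lower by a mean of -0.71 (adjusted p = 0.000220, and 0.226 with an estimated correlation), with S100a8 at -1.19 (-0.76 without CSP JUN replicate 1) and S100a9 at -0.99, which passed when adjusted over the list alone. Adipoq (1.76 ± 0.39), the leptin receptor gene Lepr (1.03 ± 0.25) and Dmp1, an osteocyte gene (2.58 ± 0.72), passed in this way too. The neutrophil genes are dim, with list means of 6.96 to 7.41 in the SSC arrays, below the medians of these arrays (7.71 to 7.76).

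In all, 48 genes were higher and 6 lower in SSC than in CSP, and 815 stood at an unadjusted p under 0.05. With each mouse as a block 8 genes passed, all higher, and with dated against undated titles as a covariate 23 did (20 higher, and lower Cep128, Epha3 and Mns1, genes outside the rule and named after their values were seen). The pericyte group did not pass with the latter (0.50) and nor did the neutrophil group (-0.62). Of the 15 named genes that passed, 8 passed in each of the 12 fits that leave out an array, 6 with the mouse block, 4 with the covariate and 3 with both of these. The count was 17 without SSC replicate 3 of the arm without JUN, 21 and 25 without CSP replicates 2 and 1 of that arm and 25 without SSC JUN replicate 2. It was 30 and 35 without CSP JUN replicates 1 and 2.

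**Figure D2:**
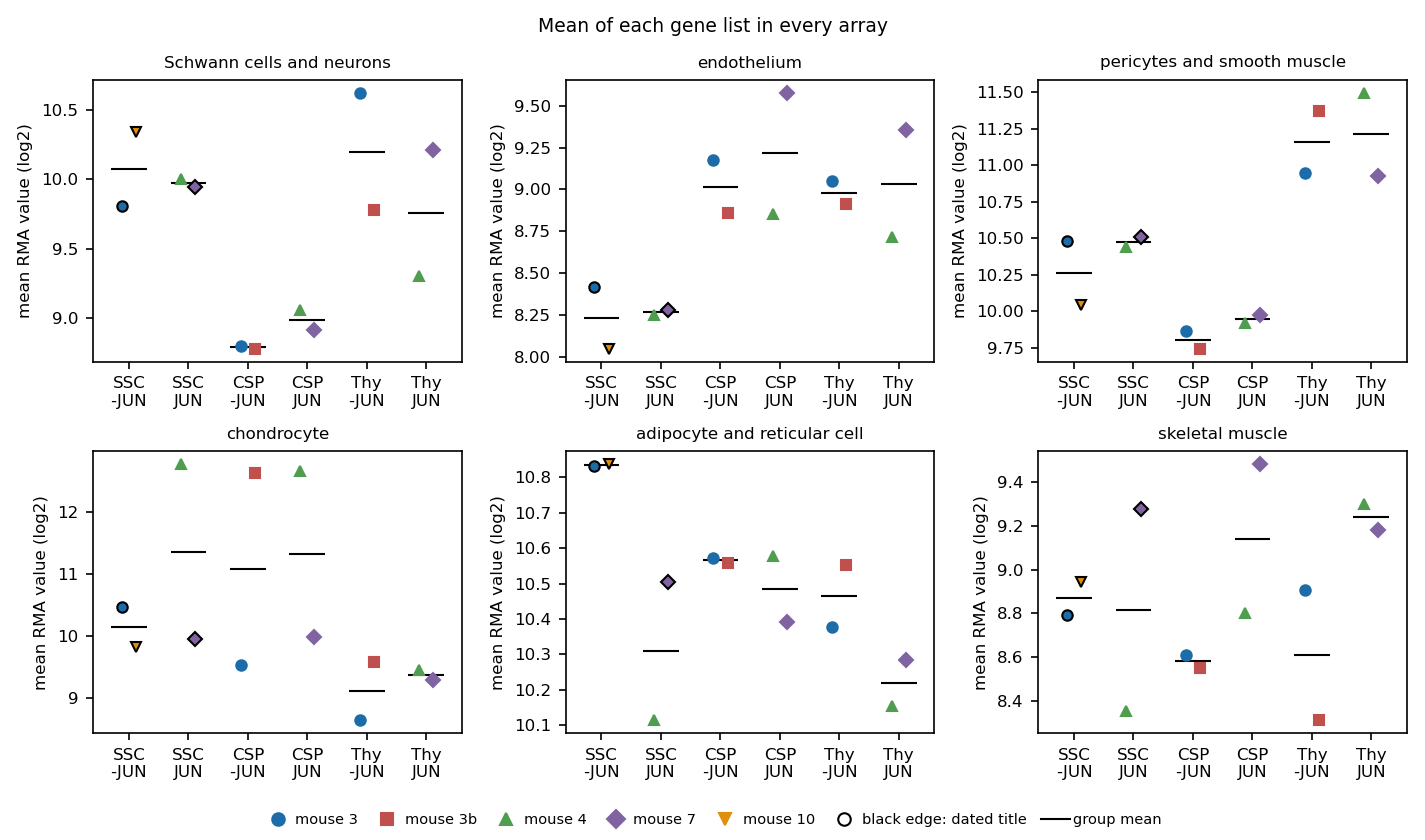
Mean log2 value of the genes of 6 lists (Schwann cells and neurons, endothelium, pericytes and smooth muscle, chondrocyte, adipocyte and reticular cell, skeletal muscle) in each of the 12 arrays, by population and induction. Each point is an array, its shape gives the mouse, a black edge marks a dated title and a line is the group mean. The Schwann list lies between 9.81 and 10.34 in the SSC arrays and between 8.78 and 9.06 in the CSP arrays, and the chondrocyte list runs from 9.53 to 12.67 within CSP.

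Against Thy, SSC had fewer transcripts of pericytes and vessels and more of cartilage. Of 14 genes of pericytes and smooth muscle 10 were lower, by a mean of -0.82 (adjusted p = 0.00474, and 0.703 with an estimated correlation). Over all genes 4 passed, and adjusted over the list alone 7 lower and 1 higher. Rgs5, a pericyte regulator of G protein signalling, fell by 3.24 (SE 0.27, adjusted p = 0.000300), and Higd1b fell by 2.50 (SE 0.26, adjusted p = 0.00154). The muscle filament gene Des (-1.30 ± 0.22) and the receptor gene Notch3 (-1.72 ± 0.29) were lower too, both at an adjusted p of 0.0379. Heyl, a target of Notch, was lower at -1.69 ± 0.30 (adjusted p = 0.0401). Of 13 endothelial genes 12 were lower, by a mean of -0.76 (adjusted p = 0.000847, and 0.479 with an estimated correlation), 2 over all genes and 6 adjusted over the list alone, with Esam at -1.61 ± 0.28 (adjusted p = 0.0379) and Eng at -1.54 ± 0.24 (adjusted p = 0.0287). Eng is also a surface marker in such sorts and the gates are not given, so its difference may be set by the sort. The selectin gene Sele (-2.42 ± 0.45, adjusted p = 0.0447) and Adgrf5 (-2.71 ± 0.43, adjusted p = 0.0296), known from vessels, were lower also.

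The remaining lower genes included Akr1c18, a steroid-metabolising enzyme gene (-4.06 ± 0.37, adjusted p = 0.000446), the collagen gene Col20a1 (-2.52 ± 0.44, adjusted p = 0.0379), Cyp4b1 (-2.43 ± 0.35, adjusted p = 0.0185) and Pi16, a gene of fibroblasts (-2.17 ± 0.40, adjusted p = 0.0447). Thy1 (-4.70 ± 0.34, adjusted p = 0.000108) shares its name with the sorted population and is no finding. Higher in SSC were Car3, a carbonic anhydrase gene (3.83 ± 0.53, adjusted p = 0.0165), Adipoq (2.42 ± 0.39, adjusted p = 0.0296), the collagen gene Col22a1 (2.23 ± 0.38, adjusted p = 0.0379), Mtm1 (1.48 ± 0.27, adjusted p = 0.0447) and the limb patterning gene Hoxd9 (1.31 ± 0.21, adjusted p = 0.0287). Each of these genes separated the 4 SSC from the 4 Thy arrays, which is a condition of being named by size. Chondrocyte genes rose as a group, 24 of 24 higher by a mean of 1.51 (adjusted p = 3.16e-07, and 0.748 with an estimated correlation), though 0 passed over all genes or adjusted over the list alone. SSC JUN replicate 1 stands apart, with a list mean of 12.78 against 9.81 to 10.46 in the other 3 SSC arrays, and without it the difference was 0.86. With the dated titles as a covariate or without the dated arrays the difference was 3.48 and 3.42, but there the SSC level rests on that array alone. With the poly-A controls as a covariate it was 3.12. Col10a1, a gene of hypertrophic cartilage, stood at 4.18 ± 1.35, Matn3 at 2.98 ± 0.93, Hapln1 at 2.86 ± 0.82 and Col9a1 at 2.63 ± 0.75. Bone matrix genes Ibsp (2.78 ± 0.65), Dmp1 (3.24 ± 0.72) and Phex (3.16 ± 0.70) did not pass over all genes, at adjusted p of 0.0904, 0.0809 and 0.0788, and passed when adjusted over the list alone.

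Neutrophil, pan-haematopoietic and cytokine genes were lower in SSC than in Thy. All 5 neutrophil genes were lower (mean -0.91, adjusted p = 0.00266, and 0.479 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, among them Camp (-1.28 ± 0.25) and S100a9 (-1.07 ± 0.25). Neutrophil list means lay at 6.96 to 7.41 in the SSC arrays, below their array medians, and at 7.61 to 8.22 in the Thy arrays. All 6 pan-haematopoietic genes were lower (mean -0.69, adjusted p = 0.00604, and 0.703 with an estimated correlation), 1 over all genes and 3 adjusted over the list alone, with Arhgdib at -1.43 ± 0.26 (adjusted p = 0.0447). Of 17 cytokine and chemokine genes 14 were lower (mean -0.56, adjusted p = 0.00469, and 0.479 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, with the monocyte attractant Ccl2 at -1.10 ± 0.21 and the macrophage growth factor Csf1 at -0.99 ± 0.26. Lists of macrophages and monocytes (mean -0.43, adjusted p = 0.310), the interferon response (-0.24, 0.355), antigen presentation (-0.34, 0.0846) and B lymphoid cells (-0.19, 0.622) did not pass. Gap43, a gene of growing nerve fibres, stood at -1.14 ± 0.30 and passed adjusted over its list alone.

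Of the 49 genes that differed between SSC and Thy 9 were higher and 40 lower in SSC, and 2210 stood at an unadjusted p under 0.05. This count moved most of the 3 population comparisons. With each mouse as a block 4 genes passed (Akr1c18, Higd1b, Rgs5 and Thy1, all lower), with the dated titles as a covariate 10, and with a covariate for the poly-A labelling controls 0 in limma. The controls read 8.72, 10.2 and 9.14 in the 3 dated SSC arrays, 11.2 in the undated SSC array and 11.2 to 12.3 in the Thy arrays. Without SSC JUN replicate 1, the undated array, 304 genes passed, without SSC replicates 3 and 1 of the arm without JUN 4 and 10, and without SSC JUN replicate 2, 5. Without Thy replicates 2 and 1 of the arm without JUN it was 8 and 15, without Thy JUN replicate 1, 11, without CSP replicates 2 and 1 of the arm without JUN 9 and 20, and without CSP JUN replicate 1, 26. Of 20 named genes that passed, Akr1c18, Higd1b, Rgs5 and Thy1 passed in all 12 such fits.

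Compared with Thy, CSP again had pericyte genes low, and cartilage genes were high in 2 of the 4 CSP arrays. Of 14 genes of pericytes and smooth muscle 12 were lower, by a mean of -1.31 (adjusted p = 5.23e-13, and 0.0861 with an estimated correlation), and 7 passed over all genes and 12 adjusted over the list alone. Rgs5 fell by 2.66 (SE 0.27, adjusted p = 0.00132), Higd1b by 2.36 (SE 0.26, adjusted p = 0.00225), the adhesion gene Mcam by 1.95 (SE 0.30, adjusted p = 0.00863) and Des by 1.16 (SE 0.22, adjusted p = 0.0259). Of 24 chondrocyte genes all 24 were higher, by a mean of 1.97 (adjusted p = 5.23e-13, and 0.637 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone, with Matn3 at 3.85 ± 0.93, Hapln1 at 3.10 ± 0.82, Col9a1 at 3.06 ± 0.75 and the joint lubricant gene Prg4 at 2.70 ± 0.72. The list means were 12.64 and 12.67 in CSP replicate 2 without JUN and CSP JUN replicate 1, 9.53 and 9.97 in the other 2 CSP arrays, and 8.63 to 9.58 in the Thy arrays. Without each of the 2 high arrays in turn the difference was 1.32 and 1.53. Schwann cell and neuron genes were lower in 8 of 12 (mean -1.09, adjusted p = 0.000487, and 0.449 with an estimated correlation), 4 over all genes and 6 adjusted over the list alone. Sox10 (-3.06 ± 0.35, adjusted p = 0.00272), Mal (-2.91 ± 0.43, adjusted p = 0.00816), Mbp (-2.88 ± 0.52, adjusted p = 0.0217) and Gap43 (-1.66 ± 0.30, adjusted p = 0.0216) passed.

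Further genes lower in CSP were Akr1c18 (-4.75 ± 0.37) and Reln (-4.10 ± 0.30), both at an adjusted p of 7.69e-05, Ednrb (-3.62 ± 0.43, adjusted p = 0.00388) and Gjc3 (-3.30 ± 0.42, adjusted p = 0.00531). Others were Col20a1 (-3.29 ± 0.44, adjusted p = 0.00547), Dhh (-3.25 ± 0.48, adjusted p = 0.00749), Cmah, an enzyme of sialic acid synthesis (-3.07 ± 0.61, adjusted p = 0.0365), and Pi16 (-2.79 ± 0.40, adjusted p = 0.00727), with Thy1 at -4.51. Esam (-1.67 ± 0.28, adjusted p = 0.0142), Arhgdib (-1.65 ± 0.26, adjusted p = 0.0111) and the macrophage growth factor Il34 (-1.24 ± 0.25, adjusted p = 0.0373) were lower as well. In CSP, Car3 (2.88 ± 0.53, adjusted p = 0.0233), Stk26, a kinase gene (2.57 ± 0.43, adjusted p = 0.0142), the protease gene Htra4 (2.33 ± 0.41) and Col22a1 (2.18 ± 0.38), both at 0.0193, were higher. So were Smoc1, a calcium-binding matrix protein gene (1.95 ± 0.32, adjusted p = 0.0128), Bmper, a secreted modulator of BMP (1.45 ± 0.22, adjusted p = 0.00828), Egfl6 (1.42 ± 0.26, adjusted p = 0.0233) and the tendon gene Tnmd (1.18 ± 0.18, adjusted p = 0.00816). All of these genes separated the 4 CSP from the 4 Thy arrays, which is a condition of being named by size.

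As groups, Notch pathway genes were lower and BMP pathway genes higher in CSP than in Thy. Of 13 Notch pathway genes 8 were lower (mean -0.51, adjusted p = 0.0282, and 0.988 with an estimated correlation), with Heyl (adjusted p = 0.0245) and Notch3 (adjusted p = 0.0429) passing and 4 adjusted over the list alone, Nrarp at -1.86 ± 0.43 and Jag1 at -0.91 ± 0.23 among them. Of 25 BMP pathway genes 17 were higher (mean 0.23, adjusted p = 0.0282, and 0.637 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone, the receptor gene Bmpr1b (1.14 ± 0.29). Notch3 is also a member of the pericyte and smooth muscle list, which had a mean of -1.31, and whether the Notch group differs apart from that list was not tested. The Notch group did not pass without Thy replicate 2 of the arm without JUN (-0.44), Thy JUN replicate 1 (-0.40) or CSP JUN replicate 2 (-0.53), nor the BMP group without Thy replicate 1 or CSP replicate 2 of the arm without JUN (0.21 and 0.17) or without Thy JUN replicate 2 (0.20).

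Of the 124 genes that differed between CSP and Thy 11 were higher and 113 lower in CSP, with 1496 at an unadjusted p under 0.05. With each mouse as a block 125 passed, and 94 of these were among the 124. The count was 52 without CSP JUN replicate 1, 64 and 75 without Thy replicates 1 and 2 of the arm without JUN, 67 and 70 without CSP replicates 2 and 1 of that arm, and 20, all lower, with the poly-A covariate. Of 30 named genes that passed, 16 passed in each of the 12 leave-out fits, and 27 did with the mouse block.

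**Figure D3:**
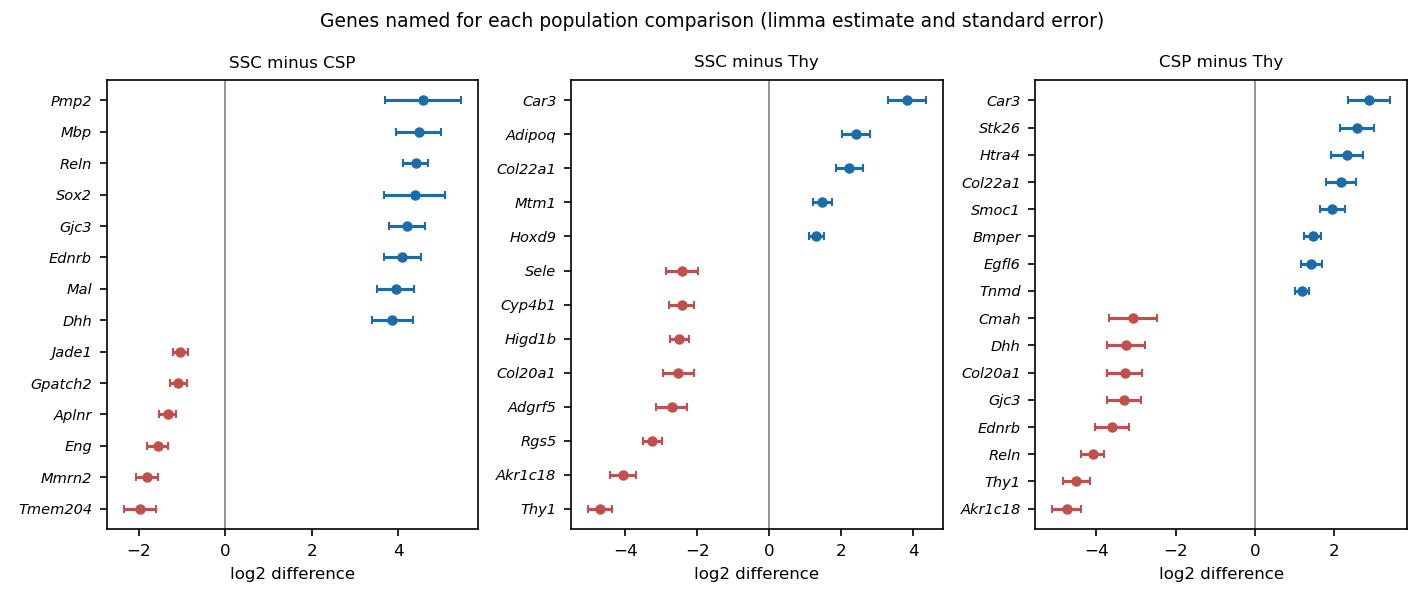
Log2 difference estimated by limma, with its standard error as a bar, for the genes named by their size in the 3 population comparisons, 4 arrays against 4, with blue for higher and red for lower in the first-named population. Values run from -4.75 for Akr1c18 in CSP against Thy to 4.58 for Pmp2 in SSC against CSP.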

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

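The tests on glial, chondrocyte and muscle genes, on differences of the JUN effect between populations for gene lists, on probe sets without a gene symbol and on splits of 2 populations at an unadjusted p were chosen after the results were seen. The other counts over splits of the arrays were set before.

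Between populations, 17 of 120 differences of a list's mean JUN effect passed at adjusted p from 0.00512 to 0.0457, and none did with an estimated correlation (adjusted p = 0.934 for each, lowest unadjusted p 0.0110). From SSC to CSP the effect was lower for immediate early genes (by -0.67), the AP-1 family (-0.61), the hedgehog (-0.47) and TGF-beta (-0.45) pathways, IGF signalling (-0.43), collagens (-0.33) and chondrocyte genes (-0.99). It was higher for adipocyte and reticular genes (0.44), oxidative phosphorylation (0.25) and skeletal muscle (0.62). From SSC to Thy it was lower for immediate early genes (-0.61) and osteoblast genes (-0.65) and higher for skeletal muscle (0.69). From CSP to Thy it was lower for mitosis (-0.33), S phase (-0.40), cytosolic ribosomal proteins (-0.23) and Schwann cell and neuron genes (-0.64). Without SSC JUN replicate 1, 3 such differences passed.

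Probe sets with no gene symbol are used in no comparison of the report. Of 2914 that passed the filter, 9 differed between SSC and CSP, all higher in SSC, 158 between SSC and Thy (145 higher in SSC and 13 lower) and 9 between CSP and Thy, all lower in CSP. The share between SSC and Thy was 5.42%, against 0.391% of the named genes, each fitted and adjusted as a separate set. At an unadjusted p under 0.05 in limma the shares lay far closer, with 688 of the 2914 probe sets and 2210 of the 12516 genes. With the dated titles as a covariate the counts of probe sets past the adjusted threshold were 0, 1 and 12, and with the mouse as a block 3, 0 and 8.

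Glial genes, taken as a list mean, were higher in each SSC array than in each CSP array. The Schwann cell and neuron list had a mean of 9.81 to 10.34 in the SSC arrays, 8.78 to 9.06 in CSP and 9.31 to 10.63 in Thy. A processing day marked by the dated titles cannot be told apart from a difference of the population, since a single SSC array is undated, though it lay 0.95 above the highest CSP array. With the dated titles as a covariate Sox10, Reln, Gjc3 and Dhh passed, while Mbp (4.47 ± 0.52 before, 4.27 ± 0.87 after), Mal (3.93 ± 0.43 and 3.37 ± 0.70) and Ednrb (4.09 ± 0.43 and 3.89 ± 0.72) did not, mainly through larger errors. Schwann cells among the sorted cells may account for it and cannot be told apart from expression by the SSC themselves, as 3 of 7 glial genes (Mbp, Sox10 and Mal) were higher in all SSC than in all CSP arrays and 6 had a higher mean. S100b, Ncam1, Gap43 and Pmp22 did not separate the populations, with CSP means of 9.64, 12.16, 10.50 and 13.62, and Ncam1 was lower in SSC (12.07). Whether such levels in CSP could hide a small share of Schwann cells was not tested. The gates used to sort are not given in the sources used here.

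Chondrocyte genes stood high in single arrays, with list means of 12.64 and 12.67 in CSP replicate 2 without JUN and CSP JUN replicate 1, 12.78 in SSC JUN replicate 1 and 8.63 to 10.46 in the other 9. The high arrays are all the SSC and CSP arrays of mice 3b and 4. In Thy these mice read 9.58 and 9.45, and the other mice 8.63 and 9.28. Whether the mouse accounts for the high values was not tested. Within CSP, JUN induction is argued against, because the arrays without JUN differed by 3.12 between replicates 2 and 1. The dated titles are argued against there too, by a range of 3.14 over the 4 undated CSP arrays. Neither is decided for SSC JUN replicate 1, since the high SSC array is also the single undated one and is labelled JUN. A varying share of chondrocytes in the sorted cells cannot be told apart from progenitors that express these genes themselves. Of the 24 genes 24 were higher in CSP replicate 2 than in replicate 1 without JUN, but this follows from the difference of the list means between the same arrays and decides neither.

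Skeletal muscle genes were higher with JUN in CSP and Thy, by means of 0.56 and 0.63 over 11 genes. Muscle RNA in the arrays of mouse 7 may account for it in CSP, where the mean dropped to 0.22 without that array. In Thy it is argued against by a mean of 0.69 without the array of mouse 7, which rests on a single JUN array. Without Thy replicate 2 of the arm without JUN the mean was 0.34. In SSC the array of mouse 7 also had the highest list mean, at 9.28 against 8.35 to 8.94 in the other SSC arrays. Muscle fibres among the sorted cells cannot be told apart from an effect of JUN in Thy, where 4 of the 5 most abundant muscle genes (Acta1, Tnnc2, Myl1 and Tnnt3, but not Ckm) were higher in both JUN arrays. An effect of JUN on the sorted cells was not tested apart from these.

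At an adjusted p under 0.05 the real grouping alone, 1 of 35 splits of the 8 arrays, gave as many genes for SSC against CSP and CSP against Thy (54 and 124, against at most 0 and 1 in the others). This excludes chance for these counts only where the shared mice are ignored. At an unadjusted p under 0.05 chance is not excluded, since 9 and 3 of the 35 splits gave as many genes as the real one (815 and 1496, highest other 1613 and 2523). For SSC against Thy chance cannot be excluded by either count, as 2 of 35 splits gave 49 genes or more, and 5 gave 2210 or more at an unadjusted p (highest other 3539). The other split past 49 gave 227 genes, which points to a structure of the samples. It sets the 3 dated SSC arrays and Thy JUN replicate 2, which shares mouse 7 with SSC JUN replicate 2, against the rest. The dated titles alone do not give this count, since the other 3 splits that keep the dated arrays together and exchange a single Thy array gave 2, 0 and 0 genes. With the dated titles as a covariate 10 genes passed, and with each mouse as a block 4. Among the 8 splits that part as many mouse pairs as the real one, 1 was as large in each comparison and the highest other gave 0, 1 and 1 genes, while the remaining splits gave at most 0, 227 and 1. These 8 splits are too few for a share under 0.05, and with each mouse as a block 8 genes passed for SSC against CSP and 125 for CSP against Thy. For the JUN effect averaged over the populations, 7 of 100 splits drawn from 108 gave as many genes at an unadjusted p under 0.05 as the real one (1569 without the mouse block, highest other 1953), so chance is not excluded. Each other split with as many genes put 1 mouse or more in both states, unlike the real one. The other drawn splits that kept each mouse in 1 state gave 440 and 781 genes, too few splits for a share.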

How the results depend on the processing

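The covariates for sex and for the poly-A controls, the fits without the dated arrays, the leave-outs of a mouse with no mouse block, the list tests with a mouse left out, and all list tests on the population comparisons and on differences of the JUN effect between populations were chosen after the data were seen. Leaving out an array can leave an arm with 1 sample, which is then assumed to vary like the other groups. The cause of a changed value was not tested unless stated, and fewer arrays by themselves lower a count.

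No alternative other than leaving out an array or a mouse gave a gene past the threshold for an effect of JUN in SSC, CSP or Thy, for the average or for the interaction. Over the fits that leave out an array, 0 to 1 genes passed in SSC and 0 in CSP, Thy and the interaction, and 0 to 1537 did for the average, mice included. The difference of Jun ranged from -0.20 to 0.85 in SSC, from -0.69 to 0.15 in Thy and from -0.34 to 0.087 on average.

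For SSC against CSP (54 genes) the counts over leave-outs of an array were 17 to 62. They were 156 with array weights, 8 with each mouse as a replicate block, 1 in arrays without JUN (Reln), 23 with the dated titles as a covariate and 17 without the dated arrays. For SSC against Thy (49 genes) leave-outs gave 4 to 304. The other counts were 74 with arrays centred on their median, 24 with no filter, 75 with the mean of a gene's probe sets, 572 with array weights, 4 with the replicate block, 8 with 6 group means, 19 in arrays without JUN, 10 with the dated titles as a covariate, 1 without the dated arrays (Ncan), 25 with the sex covariate and 0 in limma with the poly-A covariate. For CSP against Thy (124 genes) leave-outs gave 52 to 155, array weights 321, arrays without JUN 50 and the poly-A covariate 20.

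The number of lists that passed for JUN in SSC (2 of 40) was 4 with no filter, 1 with the sex covariate, 1 with the poly-A covariate, 0 with an estimated correlation and 0 to 8 over leave-outs. In CSP (2) it was 1 with no filter, 7 with the poly-A covariate, 0 with an estimated correlation and 2 to 9 over leave-outs. In Thy (1) it was 0 with an estimated correlation and 0 to 3 over leave-outs. On average (0) it was 1 with no filter, 2 with the replicate block by number, 1 with the sex covariate and 0 to 5 over leave-outs. For SSC against CSP (10) it was 6 with the poly-A covariate, 0 with an estimated correlation and 7 to 17 over leave-outs. For SSC against Thy (9) it was 21 with the dated covariate, 21 without the dated arrays and 0 with an estimated correlation. For CSP against Thy (7) it was 11 with the poly-A covariate, 0 with an estimated correlation and 4 to 9 over leave-outs. Of the differences between populations (17), 0 passed with an estimated correlation and 3 to 25 over leave-outs.

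Some list means turned sign. With the sex covariate these were skeletal muscle in SSC (0.031), AP-1 targets in CSP (-0.068), chondrocyte genes in CSP (-0.33) and Thy (-0.31) and the AP-1 family on average (-0.10). With the poly-A covariate they were AP-1 targets (-0.21) and chondrocyte genes (-0.59) in SSC, AP-1 targets (-0.20) and chondrocyte genes (-0.91) in CSP, and the AP-1 family (-0.22) and its targets (-0.17) on average. That covariate also turned Lpl to 0.50 in SSC and 0.42 on average, Sox6 to -0.25 and Col11a2 to -0.51 in SSC. For SSC against CSP, the dated covariate turned immediate early genes to 0.46, collagens to 0.20 and oxidative phosphorylation to -0.046, and leaving out the dated arrays turned them to 0.48, 0.21 and -0.053. For SSC against Thy oxidative phosphorylation turned to -0.055 with the dated covariate and to -0.062 without the dated arrays. In the fits with the dated covariate or without the dated arrays, the SSC level rests on SSC JUN replicate 1 alone.

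Over leave-outs the AP-1 family mean ranged from -0.15 to 0.998 in SSC, -0.48 to 0.12 in CSP, -0.52 to 0.33 in Thy and -0.27 to 0.38 on average. The AP-1 target mean ranged from -0.042 to 0.54 in SSC, -0.30 to 0.47 in CSP, -0.057 to 0.38 in Thy and -0.11 to 0.45 on average. Chondrocyte means ranged from -0.19 to 2.65 in SSC, -1.32 to 1.79 in CSP and -0.22 to 0.73 in Thy, and skeletal muscle in SSC, at -0.05 in all arrays (adjusted p = 0.696), from -0.52 to 0.41. Of the alternatives that keep all arrays, quantile normalisation and a trended and robust prior kept each of the 8 gene counts within 1.5 times. Signal over background per probe set was not analysed here, so how far dim genes limit the counts is given only by the filter.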

Other observations

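The list tests on the population comparisons were chosen after the data were seen, and so was the reading of them here.

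SSC had lower values than CSP for genes of DNA replication. They also had lower values for genes of early response and higher ones for respiration. Both turned with the dated titles as a covariate or without the dated arrays, where the SSC level rests on SSC JUN replicate 1 alone. That array read 12.69 in the immediate early list, against 11.62 to 11.79 in the other SSC arrays. The turn thus cannot separate a processing day from that array. Of 28 S phase genes 23 were lower (mean -0.26, adjusted p = 0.00193, and 0.634 with an estimated correlation), and of 18 immediate early genes outside AP-1 17 were lower (mean -0.38, adjusted p = 0.00266, and 0.847 with an estimated correlation). Of 23 fibroblast, periosteum and tendon genes 19 were lower (mean -0.25, adjusted p = 0.00549, and 0.294 with an estimated correlation), and of 23 collagen genes 21 (mean -0.22, adjusted p = 0.00587, and 0.847 with an estimated correlation). Of 32 genes of oxidative phosphorylation 28 were higher (mean 0.14, adjusted p = 0.00508, and 0.847 with an estimated correlation), as were 5 of 6 osteocyte genes (mean 0.79, adjusted p = 0.0333, and 0.506 with an estimated correlation). In these lists 0 genes passed over all genes, and adjusted over the list alone only Dmp1 did. Immediate early genes did not pass without CSP replicate 2 of the arm without JUN (-0.24), without CSP JUN replicate 1 (-0.27) or with the replicate block (-0.15), fibroblast genes without SSC JUN replicate 1 (-0.22). Collagens did not pass without SSC replicate 3 (-0.11) or CSP replicate 2 (-0.17) of the arm without JUN or with the replicate block (-0.07), and oxidative phosphorylation without SSC replicate 3 (0.11) or CSP replicate 1 (0.09) of that arm or with the replicate block (0.09). With the dated titles as a covariate immediate early genes turned to 0.46, collagens to 0.20 and oxidative phosphorylation to -0.046, and without the dated arrays to 0.48, 0.21 and -0.053. Osteocyte genes did not pass without SSC replicate 3 (0.81) or CSP replicate 1 (0.64) of that arm, CSP JUN replicate 1 (0.85) or SSC JUN replicate 1 (0.61).

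Against Thy, SSC again had lower S phase genes, 19 of 28 with a mean of -0.27 (adjusted p = 0.0313, and 0.786 with an estimated correlation). The replication helicase genes Mcm2 (-0.84), Mcm3 (-0.94) and Mcm7 (-0.56) passed when adjusted over the list alone, and 0 passed over all genes. Cytosolic ribosomal protein genes were higher in 22 of 29 (mean 0.18, adjusted p = 0.00474, and 0.786 with an estimated correlation) and oxidative phosphorylation genes in 21 of 32 (mean 0.13, adjusted p = 0.0313, and 0.832 with an estimated correlation). The ribosomal group did not pass with the dated titles as a covariate (0.054), and oxidative phosphorylation then turned to -0.055. S phase did not pass without SSC (-0.27) or Thy (-0.16) replicate 1 of the arm without JUN, SSC JUN replicate 1 (-0.24) or Thy JUN replicate 2 (-0.18). Oxidative phosphorylation did not pass without SSC replicate 1 (0.12), SSC replicate 3 (0.10) or Thy replicate 2 (0.09) of that arm, SSC JUN replicate 2 (0.11) or Thy JUN replicate 1 (0.06). In CSP against Thy, cytokine and chemokine genes were lower in 13 of 17 (mean -0.38, adjusted p = 0.0282, and 0.449 with an estimated correlation), with Il34 passing over all genes and adjusted over the list alone. TGF-beta pathway genes were higher in 15 of 19 (mean 0.23, adjusted p = 0.0369, and 0.988 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The cytokine group did not pass without Thy replicate 2 of the arm without JUN (-0.33), Thy JUN replicates 1 (-0.36) or 2 (-0.35), CSP JUN replicate 2 (-0.36) or with no filter (-0.22). The TGF-beta group did not pass without CSP replicates 1 (0.20) or 2 (0.21) or Thy replicate 1 (0.18) of the arm without JUN, or without Thy JUN replicates 1 (0.16) or 2 (0.23).

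The means of the poly-A labelling controls were 8.72 to 10.2 in the 3 dated SSC arrays, 9.92 in CSP replicate 1 without JUN and 10.8 to 12.3 in the other 8. With JUN against without, they were 10.2 and 11.2 against 8.72 and 9.14 in SSC, and 11.2 and 11.7 against 9.92 and 10.8 in CSP. In Thy the arms overlapped (12.3 and 11.3 against 11.9 and 11.2). Within SSC and CSP whatever moved these controls thus cannot be told apart from JUN, and its source was not tested.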
